A study of Mus musculus with 25 samples.

How the data were processed

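Jejunum of mouse pups was sequenced in 25 libraries, 5 for each of 5 groups named in the labels: control (normal suckling), early weaning (EW), EW with 2'-FL and LNnT (EW+HMOs), EW with 2'-FL, and EW with LNnT. Per the series' design text, pups were assigned at day 14, weaned at day 15 in the EW groups, and the controls were taken at day 21. Per the labels' protocols, total RNA with a RIN above 7 was enriched for poly(A) RNA on oligo(dT) beads and made into strand-specific libraries with dUTP. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR were used with the GRCm39 genome, and the notes as available give neither roles nor order. The annotation release, the program that made the counts and the way reads shared by paralogs were assigned were not given in the sources used here. That last gap bears on pairs such as Reg3b and Reg3g, Hspa1a and Hspa1b, Hba-a1 and Hba-a2, and on the Sprr2a, Defa, Cyp2 and H2-Q families.

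The deposited gene table holds counts, whole numbers per Ensembl gene with 1 column per library, and was used for every comparison. A second deposited table holds FPKM, scaled by the authors to gene length and library size, beside a copy of the same counts, and was used only for a repeat of the tests. It also gave the gene symbols. The columns named as suckling libraries are called Control1 to Control5 here. Of 57132 genes in the count table, 35723 had a count in at least 1 library, and 22131 passed edgeR's filterByExpr by group and were tested. The 13592 genes with a count that were left out were too low for the test, and the tested genes held 99.98% of all counts. Because 235 symbols were shared by more than 1 gene, genes were kept apart by their Ensembl identifiers.

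Totals per library ranged from 58.7 to 89.6 M counts. Group means ± SD were 77.3 ± 6.66 M in control, 82.6 ± 8.11 in EW, 85 ± 2.53 in EW+HMOs, 80.5 ± 7.62 in EW+2'-FL and 75.8 ± 10.7 in EW+LNnT. Spearman correlations between libraries of the same group were 0.924 to 0.983, and no 2 libraries were copies of one another. Simulated data took their depths and their spread from the fit of all 25 libraries, and only genes with a mean above 1 CPM were changed. Between EW and control the test called 111 genes, 3 of them unchanged (2.7%). It found 5.97% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 95.5% of those changed 4-fold. Changes well under 2-fold were therefore mostly out of reach with that shared spread, and a fit with another spread has another limit.

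Analyses ran in R 4.3.3. Counts were scaled by TMM and fitted in edgeR 4.0.16 with a robust quasi-likelihood model of all 25 libraries, with 1 mean per group and no covariate, since the labels give no sex, litter or batch. The 10 pairs of groups were compared, and an 11th contrast set EW+HMOs minus EW against the sum of the 2 single-oligosaccharide changes. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. Expression is given in CPM (counts scaled to library size) as mean ± SD, and changes as log2 estimates ± standard error. The groups, contrasts, tests, gene lists, named-gene rule and other settings were chosen before the data were examined.

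Gene lists numbered 44, with 570 genes of which 551 were tested. Each list was tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01 and adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. For EW against control the estimated correlation was 0.46 for cholesterol synthesis, 0.22 for detoxification, 0.77 for erythroid and 0.01 for retinoid genes. Where it lies far above the preset, the preset p values can be far too small. In simulated data with 1 list raised, the preset test also called 2 unchanged lists. Camera with an estimated correlation and fry each called 1. Members were counted as called over all genes tested and also adjusted over the list alone. A list score is the mean log2 CPM of its genes in 1 library, and scores were compared by exact permutation of the libraries.

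Genes were named by a fixed rule. It took, for contrasts against EW or control and for 2'-FL against LNnT, up to 8 rises and 8 falls with the largest log2 change among called genes with at least 5 CPM in the higher group and all libraries of one group on the same side of the other group's mean. It added up to 4 called members with the smallest p from each list that passed or had 3 or more called members, and a panel given whether called or not (Lct, Sis, Tjp1, Ocln, Cldn3, Muc2, Reg3g, Tnf, Il1b and Il6). Predicted genes were left out, and Il6 was too low to test. The text gives part of the named genes for the supplement groups against controls. Means of list members outside the rule, such as Slc5a1, Anpep, Hbb-bs and Alas2 against EW and the interval for Lgr5, Nfil3 and Per2 between the single oligosaccharides, were chosen after their values were seen.

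The share of early-weaning genes moved back was measured against simulated unchanged groups and with EW and control libraries split in 2 parts, and correlations between supplement groups were set against the same kind of simulation. The plan was to use the genes called in each split, and because few passed, the 211 with the smallest p were used, with the called genes given beside them. Other settings fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma voom with quality weights, no count filter and a stricter one (more than 1 CPM in 5 libraries), a fit of the 2 groups alone, a 2-fold or 0.01 threshold, the replicate number as a block, limma on log2 FPKM with pseudocounts of 1 and 0.1, and each library left out in turn. Chosen after seeing the data were a Y-linked share as a covariate, fits of libraries with Y-linked transcripts or Xist alone, and fits without the 6 libraries with pancreatic transcripts or without FL1, LNnT1 and LNnT2. Each count was also set against 100 splits of the libraries into mock groups. No library was left out of the tests given first.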

Results

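Jejunal mRNA was compared across 25 mouse libraries, 5 in each of 5 groups: suckling controls taken at postnatal day 21, pups weaned early at day 15 (EW), and early-weaned pups given 2'-fucosyllactose and lacto-N-neotetraose together (EW+HMOs), 2'-fucosyllactose alone (EW+2'-FL) or lacto-N-neotetraose alone (EW+LNnT). Doses and the day on which the early-weaned groups were taken were not given in the sources used here. The labels do not say that each library came from a separate animal, so the p-values measure only the spread between these samples. Xist, the transcript of the silenced X chromosome, marked 4 control libraries, and the fifth (Control2) held both Xist and Y-linked transcripts. Libraries with Y-linked transcripts made up 4 of 5 in EW, 3 in EW+HMOs, 4 in EW+2'-FL and 2 in EW+LNnT. Transcripts of pancreatic acinar cells took 0.139% of the counts in Control2, 1.32% in Control3, 0.488% in Weaned1, 0.685% in FL5, 2.1% in LNnT1 and 0.632% in LNnT2, and at most 0.00221% in any other library.

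The first principal component held 22.4% of the variance and set FL1, LNnT1 and LNnT2 (119.4 to 171.9) apart from the other 22 libraries, and the second held 11.6%. Weaned1 came next on the first component, at 57.4, against at most 11.3 in the rest. In these 3 libraries the mean log2 CPM of the circadian clock genes was 6.03 to 6.24, against 4.01 to 5.14 elsewhere, and that of glucocorticoid-induced genes was 8.24 to 8.31, against 5.74 to 7.46. Lymphocyte and antigen-presentation transcripts were lower in the same libraries: T cell genes lay at -2.82 to -1.98 (-0.67 to 1.61 elsewhere), MHC class II genes at 2.71 to 3.04 (3.75 to 4.95) and interferon-induced genes at 2.29 to 2.65 (3.23 to 5.16). The same libraries had the highest mitochondrial shares of counts (8.98% to 9.57%, against at most 7.93% elsewhere) and the lowest TMM factors (0.845 to 0.905, against at least 0.915), and their 10 largest genes took 13.3% to 13.6% of counts, a share that only Weaned1 exceeded (15.4%).

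**Figure D1:**
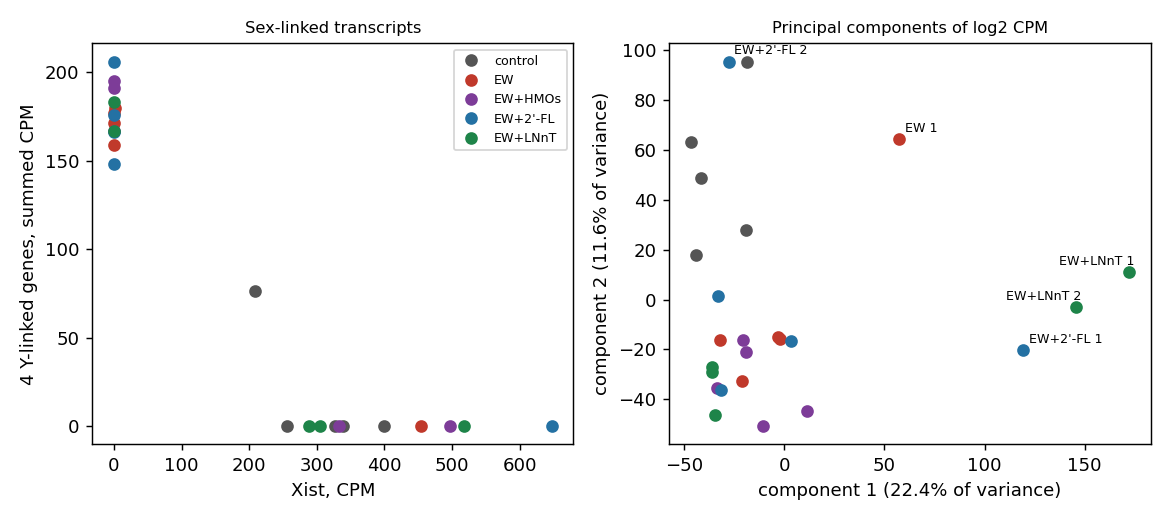
Sex-linked transcripts and principal components of the 25 libraries. On the left, the summed CPM of 4 Y-linked genes against Xist, and on the right the first 2 components of log2 CPM. Each point is 1 library, coloured by group (n = 5 per group).

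Early weaning came with higher expression of cholesterol synthesis genes and of the lectins Reg3b and Reg3g, and with lower expression of genes that metabolise foreign compounds. These lectins, which are secreted and act against gut bacteria, rose from 102 ± 55.5 to 2420 ± 1520 CPM (mean ± SD, n = 5 per group; log2 change 4.58 ± 0.64, estimate ± standard error) and from 23.2 ± 11.1 to 528 ± 340 CPM (4.51 ± 0.69). The antimicrobial list that holds them did not pass (2 of 17 genes called; median 0.19; camera adjusted p = 0.72). Lss (lanosterol synthase) rose 3.33-fold (1.74 ± 0.24), Fdps (farnesyl diphosphate synthase) 3.22-fold (1.69 ± 0.27) and Mvd (mevalonate diphosphate decarboxylase) 2.72-fold (1.44 ± 0.21). Cyp1a1, a target of the aryl hydrocarbon receptor that oxidises aromatic compounds, fell from 68.4 ± 79.7 to 2.61 ± 2.22 CPM (-4.71 ± 0.93). Control5 held 206 CPM and the other controls 8.55 to 59.5, and without Control5 the change was -3.70 and did not pass. Ass1, the argininosuccinate synthase of the suckling enterocyte, fell from 13.6 ± 2.97 to 3.03 ± 0.63 CPM (-2.16 ± 0.29). In edgeR the adjusted p values were 0.00078 for Reg3b, 0.0014 for Reg3g, 0.00067 for Lss, 0.0017 for Fdps, 0.001 for Mvd, 0.014 for Cyp1a1 and 0.00042 for Ass1.

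Of the 21 cholesterol synthesis genes, 12 rose in EW and none fell, and 17 rose when adjusted over the list alone (median log2 change 1.06; camera adjusted p = 1.1e-30 with the preset correlation, and adjusted p = 0.027 with an estimated correlation). Of 16 detoxification genes, 4 fell, and 10 fell when adjusted over the list alone (median -0.69; camera adjusted p = 1.3e-10). It gave adjusted p = 0.043 with an estimated correlation. These included the phenobarbital-inducible cytochrome Cyp2b10 (-1.56 ± 0.21), the retinaldehyde dehydrogenase Aldh1a1 (-1.86 ± 0.45), the carboxylesterase Ces2a (-2.01 ± 0.45) and Cyp2c55 (-2.14 ± 0.52). Fatty acid oxidation genes had 4 of 20 members lower and none higher, with 9 lower when adjusted over the list alone (median -0.39; camera adjusted p = 6.1e-08). The value was adjusted p = 0.26 with an estimated correlation. Among them were the carnitine carrier Slc25a20 (-0.78 ± 0.17), the mitochondrial enzymes Hadhb (-0.57 ± 0.13) and Acadm (-0.50 ± 0.12), and Cyp4a10 (-2.40 ± 0.59, and -3.04 without Weaned1). Among 11 Paneth cell genes, 3 rose, and 5 rose when adjusted over the list alone (median 0.57; camera adjusted p = 1.2e-06). This became adjusted p = 0.35 with an estimated correlation. These were the phospholipase Pla2g2a (1.57 ± 0.26), the defensin Defa22 (1.57 ± 0.35) and Mmp7, the protease that activates defensins (1.35 ± 0.32).

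Suckling-type enterocyte genes had 2 of 9 members lower, Ass1 and the neonatal Fc receptor Fcgrt (-0.85 ± 0.18), and the same 2 when adjusted over the list alone (median -0.36; camera adjusted p = 0.0024). The list had adjusted p = 0.071 with an estimated correlation. In the retinoid list 2 of 11 genes fell, Aldh1a1 and Rdh7 (-0.95 ± 0.21), and 3 when adjusted over the list alone (median -0.31; camera adjusted p = 0.0067). Camera gave adjusted p = 0.069 with an estimated correlation. The clock list had 1 member higher of 15, Hlf (1.17 ± 0.21), and 2 when adjusted over the list alone (median 0.50; camera adjusted p = 0.0011). It gave adjusted p = 0.55 with an estimated correlation. Haemoglobin and other erythroid genes had no called member of 6, but 5 higher when adjusted over the list alone (median 1.29; camera adjusted p = 2e-04). The value was adjusted p = 0.40 with an estimated correlation. Of 44 lists, 12 passed with the preset correlation (6 up and 6 down), 2 with an estimated correlation and 5 by fry.

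In the panel of barrier and digestive genes, the claudin Cldn3 fell from 249 ± 30.5 to 151 ± 28.9 CPM (-0.72 ± 0.16; edgeR adjusted p = 0.025). Sucrase-isomaltase (Sis), the disaccharidase of the weaned gut, had a log2 change of 1.06 ± 0.30 that did not pass (edgeR adjusted p = 0.091), and lactase (Lct) one of -0.36 ± 0.35 (edgeR adjusted p = 0.70). Values for the junction genes Tjp1 and Ocln were 0.20 and -0.23, for the mucin Muc2 -0.49, and for the cytokines Il1b and Tnf -0.90 and -1.30, none of which passed. Other called genes with large changes were H2-Q10 (3.15 ± 0.34), Mbl2 (2.60 ± 0.61), the skeletal actin Acta1 (2.48 ± 0.56) and the epithelial kinase Ptk6 (2.22 ± 0.53), all higher. Acta1 stood at 29.9 CPM in Weaned3 and at most 5.48 in the other EW libraries, and without Weaned3 its change was 1.20 and did not pass. Lower genes were Mylk3 (-2.35 ± 0.35), Ankrd37 (-2.73 ± 0.45), the pentraxin Mptx1 (-2.99 ± 0.30) and Smcp (-4.01 ± 0.67). Sftpc, the lung surfactant protein C gene, had no count in any control library. It stood at 28.5 CPM in Weaned3 and at most 0.326 CPM in the other EW libraries. It was called (edgeR adjusted p = 0.03), but its fitted log2 change of 11.88 ± 2.56 leaned mainly on Weaned3.

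In total, edgeR called 211 genes between EW and control (98 higher, 113 lower, 107 of them at least 2-fold), and 3092 genes had an unadjusted p under 0.05. DESeq2 called 658, voom with quality weights 4775, and a fit of the 2 groups alone 1638. The fit without the 3 libraries apart on the first component gave 1135, and a fit with the Y-linked share as a covariate gave 55, with a median change of the 211 genes of 0.99 against 1.02 without it. Leaving out 1 library gave 119 genes without Control1, 62 without Control3, 84 without Control4, 75 without Control5, 530 without Weaned1, 77 without Weaned2, 101 without Weaned3, 58 without Weaned4 and 127 without Weaned5. Libraries of other groups, which enter through the shared fit, mattered as well, with 360 genes without FL1 and 404 without FL2.

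**Figure D2:**
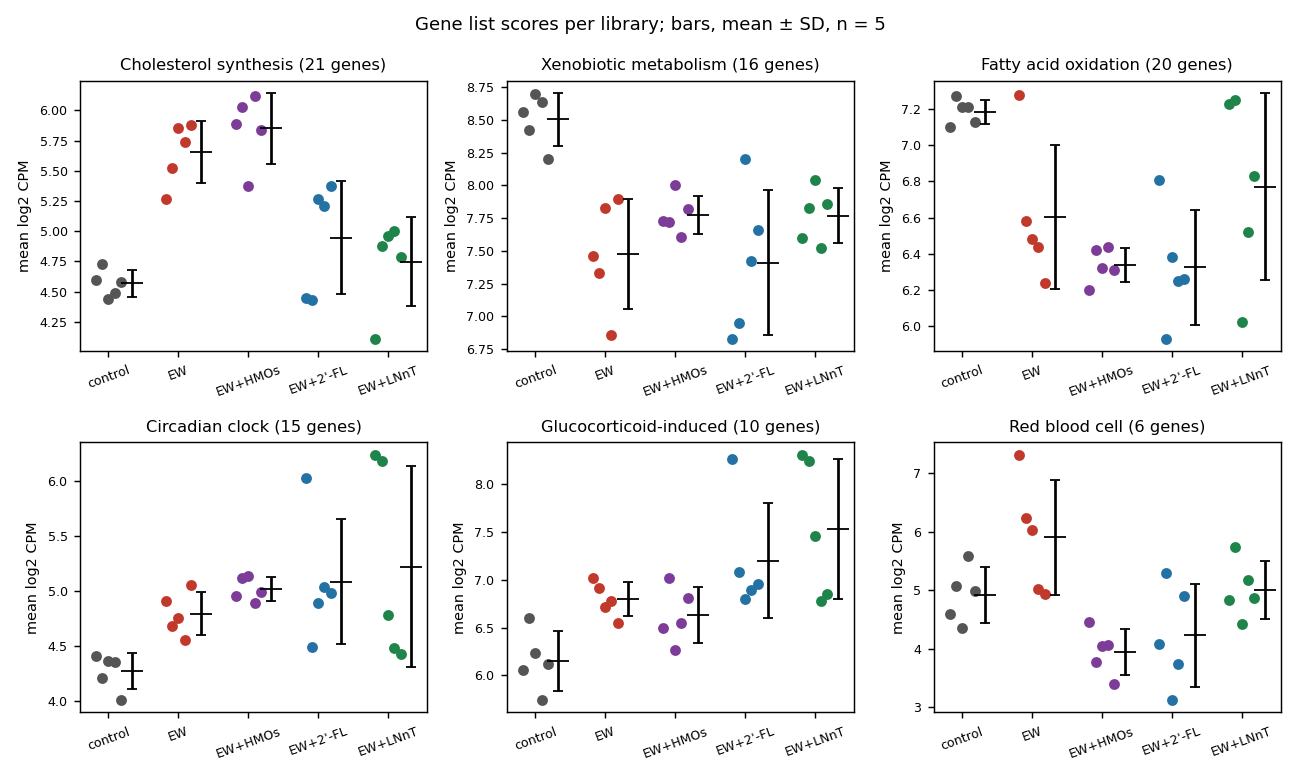
Scores of gene lists in the 25 libraries, by group, as mean log2 CPM over the genes of each list. Points are libraries (n = 5 per group), and the crosslines with bars are mean ± SD.

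LNnT given to early-weaned pups came with lower expression of the cholesterol synthesis genes that were higher in EW. Fdft1, squalene synthase, fell from 33.1 ± 4.95 CPM in EW to 11.9 ± 1.73 CPM in EW+LNnT (n = 5 per group; log2 change -1.47 ± 0.22). Mvd fell from 12.6 ± 2.53 to 5.63 ± 0.994 CPM (-1.17 ± 0.21) and Insig1, which retains SREBP in the endoplasmic reticulum, from 82.7 ± 17.1 to 38.9 ± 4.86 CPM (-1.09 ± 0.23). The edgeR adjusted p values were 0.004, 0.017 and 0.045. Of the 21 genes of the list 4 fell, and 15 fell when adjusted over the list alone (median -1; camera adjusted p = 2e-23, but adjusted p = 0.088 with an estimated correlation, and 0.0079 by fry). The list score was lower in all 5 EW+LNnT libraries (4.11 to 5) than in all 5 EW libraries (5.27 to 5.88). The exact permutation p was 0.0079, the smallest that 5 against 5 libraries can give, and 0.35 when adjusted over the lists.

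Nfil3, a transcription factor under clock control, rose 6.4-fold in EW+LNnT (2.68 ± 0.41; edgeR adjusted p = 0.0056), and the period gene Per2 1.96-fold (0.97 ± 0.19; edgeR adjusted p = 0.027). Per2 was the only clock gene of 15 called, and 7 rose when adjusted over the list alone (median 0.84; camera adjusted p = 3.7e-06). This became adjusted p = 0.51 with an estimated correlation. Glucocorticoid-induced genes had no called member of 10 and 6 higher when adjusted over the list alone (median 1.01; camera adjusted p = 0.00027). The list had adjusted p = 0.49 with an estimated correlation. Both lists were highest in LNnT1 and LNnT2, and without FL1, LNnT1 and LNnT2 the clock median was -0.20 and the glucocorticoid median 0.30, neither of which passed, while the cholesterol median was -0.98. That clock median does not show unchanged members. Per2 in LNnT3, LNnT4 and LNnT5 (99.4 to 158 CPM) still lay above every EW library (48.6 to 80.1), as did Cry1 and Clock, whereas Hlf and Per3 did not. The intestinal stem cell receptor Lgr5 fell from 13 ± 2.97 to 7.38 ± 1.54 CPM (-0.82 ± 0.17; edgeR adjusted p = 0.041) as the only called member of the crypt stem cell list (median -0.30; camera adjusted p = 0.0051), whose median was 0.05 among libraries with Y-linked transcripts. Camera gave adjusted p = 0.57 with an estimated correlation. Immediate early and heat-shock genes had no called member of 10 and 9 higher when adjusted over the list alone (median 2.14; camera adjusted p = 5.9e-05, and adjusted p = 0.57 with an estimated correlation), with a score of 9.23 in LNnT3 and at most 5.47 in any other library. Without LNnT3 this median was 0.23 and did not pass. Higher genes also included Trib1 (1.77 ± 0.32), Flrt3 (1.71 ± 0.36), the zinc exporter Slc30a1 (1.53 ± 0.32), Zbtb2 (1.38 ± 0.26), Tsc22d2 (1.33 ± 0.27), Ripk4 (1.16 ± 0.21) and Fbxo33 (1.12 ± 0.19). Flrt3 and Slc30a1 were highest in LNnT3 (99.9 and 380 CPM), without which their changes were 1.00 and 0.87 and did not pass. Tsc22d2 stood at 55.5 to 106 CPM in LNnT1, LNnT2 and LNnT3, but at 28.4 and 30.9 in LNnT4 and LNnT5 (EW 21.4 to 29.9). Ripk4 stood at 82.7 to 126 CPM in the former and at 42.3 and 52.2 in the latter (EW 31.2 to 44.3). Trib1, Zbtb2 and Fbxo33 lay above every EW library in each EW+LNnT library. Acta1 (-3.53 ± 0.59), Maged2 (-0.83 ± 0.17) and Zfp810 (-0.79 ± 0.16) were lower, with Acta1 at -2.25 without Weaned3.

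Some lists of cells outside the epithelium were also lower in EW+LNnT than in EW. Medians were -0.66 for enteric neural, -0.54 for smooth muscle, -0.26 for fibroblast and -4 for adipocyte genes, and pancreatic genes were higher (2.50). Camera adjusted p values were 0.0043, 0.0045, 0.025, 0.011 and 0.025, and 0.57 to 0.73 with an estimated correlation. Erythroid genes (median -1.11, camera adjusted p = 0.00061) and macrophage genes (-0.37, camera adjusted p = 0.002) were lower too, with adjusted p of 0.57 and 0.59 with an estimated correlation.

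None of the panel genes passed between EW+LNnT and EW. Log2 differences were 0.61 for Ocln (edgeR adjusted p = 0.19), 0.51 for Tjp1 (0.31), 0.45 for Cldn3 (0.21), 0.13 for Sis, 0.10 for Muc2, 0.07 for Lct, -0.17 for Reg3g, 1.45 for Tnf and 0.58 for Il1b. The tight junction list had no called member of 22 (median 0.16; camera adjusted p = 0.0081). It gave adjusted p = 0.57 with an estimated correlation. The edgeR count was 38 genes (26 higher, 12 lower, 20 at least 2-fold; 2521 at an unadjusted p under 0.05), with 409 in DESeq2, 156 with voom and 1 in a fit of the 2 groups alone. It was 6 with the Y-linked share as a covariate, 3 without the 6 libraries with pancreatic transcripts, and 299 without the 3 libraries apart. Without 1 library the counts were 21 genes without Weaned1, 11 without Weaned2, 7 without Weaned3, 5 without Weaned4, 17 without Weaned5, 11 without LNnT1, 10 without LNnT3, 161 without LNnT4 and 120 without LNnT5. Outside the 2 groups they were 219 without FL1, 120 without FL2 and 22 to 25 without Control2, Control3, Control4, Control5, HMOs2, HMOs4 or HMOs5.

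**Figure D3:**
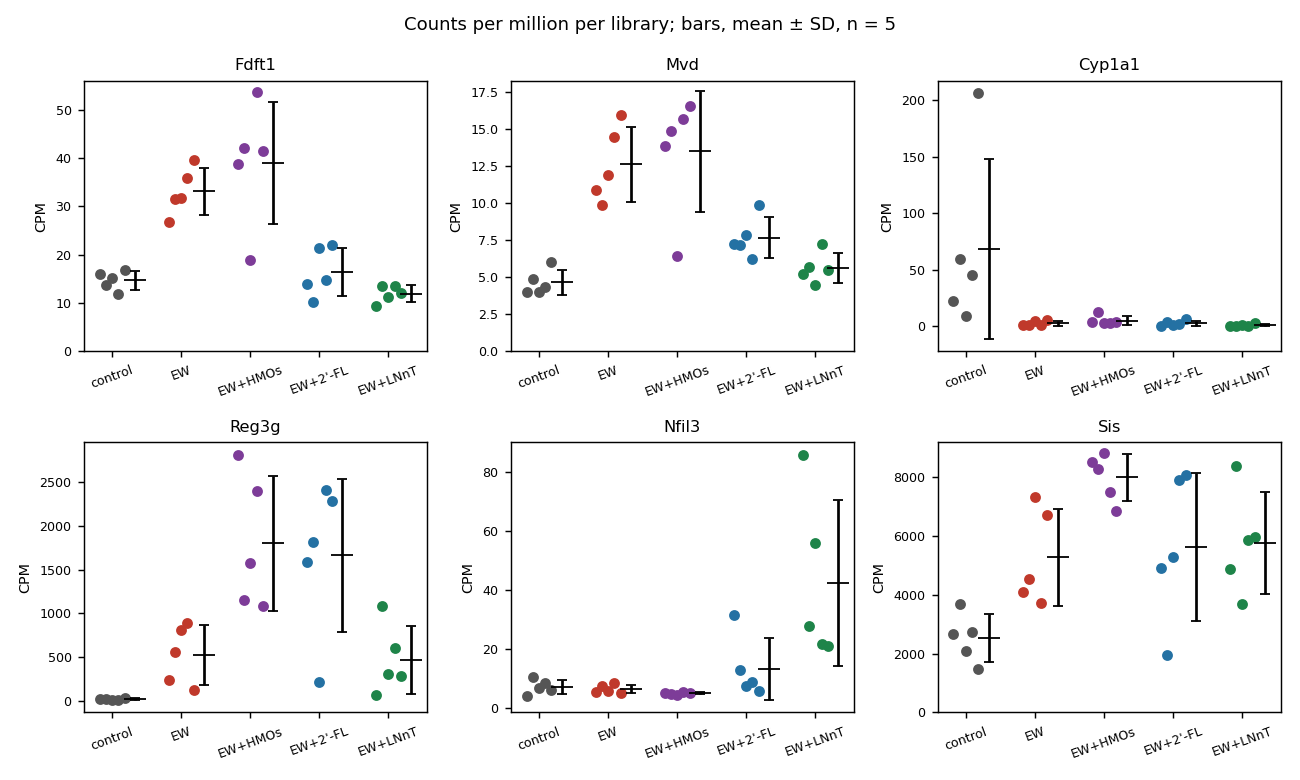
Expression of Fdft1, Mvd, Cyp1a1, Reg3g, Nfil3 and Sis in each library of the 5 groups, in CPM. Points are libraries, and bars show mean ± SD (n = 5 per group).

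With 2'-FL, no single gene passed against EW. Cholesterol synthesis genes were lower as a group. None of 21 was called, 14 fell when adjusted over the list alone (median -0.61; camera adjusted p = 1.7e-23, and adjusted p = 0.041 with an estimated correlation), and Fdft1 averaged 16.4 ± 5.07 CPM against 33.1 ± 4.95 in EW (n = 5 per group). Erythroid genes, which mark red blood cells, were lower in the same test, with none of 6 called and 5 lower when adjusted over the list alone (median -1.68; camera adjusted p = 5.3e-16). The value was adjusted p = 0.035 with an estimated correlation. Macrophage genes had a median of -0.47 (camera adjusted p = 2.7e-07, and adjusted p = 0.38 with an estimated correlation) and interferon-induced genes one of -0.29 (camera adjusted p = 7.2e-06, and adjusted p = 0.85 with an estimated correlation). The interferon score was lowest in FL1 of its group, and without FL1 the median was -0.12 and did not pass. Reg3g averaged 1660 ± 874 CPM against 528 ± 340 in EW (log2 1.65 ± 0.61; edgeR adjusted p = 0.74). Cldn3 differed by 0.32, Ocln by 0.24, Sis by 0.09, Tjp1 by 0.02, Lct by -0.32, Muc2 by -0.56, Tnf by 0.72 and Il1b by -0.59. In edgeR the count was 0 genes, with 1199 at an unadjusted p under 0.05, 48 called by DESeq2, 10 by voom and 1 by limma on the FPKM values. Leaving out Weaned5 gave 2 genes and leaving out FL4 gave 1.

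The combined oligosaccharides also left no single gene past the test against EW. Erythroid genes were lower, from 570 to 147 CPM for the beta globin Hbb-bs and from 19.2 to 4.03 CPM for Alas2, the haem synthesis enzyme of red cells. None of the 6 was called, and all 6 were lower when adjusted over the list alone (median -1.98; camera adjusted p = 7.6e-23). This became adjusted p = 0.0065 with an estimated correlation. All 14 nutrient transporters and all 13 brush-border peptidases had positive differences, with medians of 0.40 (camera adjusted p = 1.7e-09, and adjusted p = 0.22 with an estimated correlation) and 0.46 (camera adjusted p = 6.7e-08, and adjusted p = 0.22 with an estimated correlation). Some lists of cells outside the epithelium were lower in the same contrast. Medians were -0.57 for enteric neural, -0.47 for smooth muscle, -0.30 for fibroblast and -2.81 for adipocyte genes. Camera adjusted p values were 1.6e-07, 0.001, 0.019 and 7e-04, and 0.22 to 0.45 with an estimated correlation. Immune lists did not follow. T cell genes were higher (median 0.84; camera adjusted p = 3.2e-06, and adjusted p = 0.35 with an estimated correlation). MHC class II genes were higher too (median 0.40; camera adjusted p = 5.6e-05, and adjusted p = 0.29 with an estimated correlation). Macrophage (0.06) and B and plasma cell genes (0.38) did not pass. Among the transporters and peptidases, the sodium-glucose cotransporter Slc5a1 averaged 6190 CPM against 4050 in EW and the aminopeptidase Anpep 4050 against 2290. Cholesterol synthesis genes stayed near their EW level (median 0.20, and 0.07 without Weaned1; camera adjusted p = 0.0007). The list had adjusted p = 0.45 with an estimated correlation. In the panel, Reg3g averaged 1800 ± 768 against 528 ± 340 CPM (log2 1.77 ± 0.62; edgeR adjusted p = 1) and Sis 7980 ± 807 against 5260 ± 1630 (0.60 ± 0.29). Lct differed by 0.43, Muc2 by 0.31, Tjp1 by 0.01, Cldn3 by -0.12, Ocln by -0.19, Tnf by 0.64 and Il1b by 0.47. By edgeR the count was 0 genes, with 921 at an unadjusted p under 0.05, against 55 in DESeq2 and 161 with voom, and 1 gene passed without HMOs5.

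The 2 oligosaccharides differ in structure: 2'-FL is lactose carrying a fucose, and LNnT is an unfucosylated tetrasaccharide. Their doses were not in the labels, so the readouts stand side by side without a matched dose. No gene was called between EW+2'-FL and EW+LNnT, and the cholesterol synthesis genes differed little in median (0.26, not called). Log2 differences, 2'-FL minus LNnT with 95% intervals, were 0.46 (0.01 to 0.90) for Fdft1, 0.45 (0.01 to 0.88) for Mvd, and -0.18 (-0.64 to 0.29) for Insig1. They were -0.48 (-0.87 to -0.10) for Per2, -1.66 (-2.49 to -0.84) for Nfil3, 0.59 (0.24 to 0.94) for Lgr5 and 1.82 (0.55 to 3.09) for Reg3g. Barrier and digestive genes gave -0.49 (-0.91 to -0.07) for Tjp1, -0.37 (-0.77 to 0.03) for Ocln, -0.13 (-0.45 to 0.19) for Cldn3, -0.03 (-0.64 to 0.57) for Sis and -0.39 (-1.12 to 0.34) for Lct, and the smallest edgeR adjusted p of any gene was 0.34. The intervals lay within 2-fold either way for 52.6% of the tested genes, so larger differences remained possible for the rest. Crypt stem cell genes had a median of 0.35 (camera adjusted p = 0.00055, and adjusted p = 0.57 with an estimated correlation), fatty acid oxidation genes one of -0.35 (camera adjusted p = 1.9e-05, and adjusted p = 0.57 with an estimated correlation) and immediate early genes one of -2.15 (camera adjusted p = 0.00015, and adjusted p = 0.57 with an estimated correlation), the last with LNnT3 far above the other libraries and a median of 0.01 without it. The fatty acid oxidation median was -0.12 without the 3 libraries apart and did not pass. Among libraries with Y-linked transcripts the medians of the crypt and immediate early lists were 0.01 and 0.33. Smooth muscle (median 0.70), adipocyte (4.34) and enteric neural genes (0.51) were higher with 2'-FL, and tight junction genes lower (-0.17). Camera adjusted p values were 0.0058, 0.0058, 0.023 and 0.0058, and 0.57 to 0.68 with an estimated correlation. Without FL2 the smooth muscle median was -0.05. The edgeR count was 0 genes, with 1884 at an unadjusted p under 0.05, against 86 in DESeq2 and 0 with voom, and 4 genes passed without FL1.

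Cholesterol synthesis genes were higher in EW+HMOs than with either oligosaccharide alone. Against EW+2'-FL none of 21 was called and 19 were higher when adjusted over the list alone (median 0.82; camera adjusted p = 2.2e-29). Camera gave adjusted p = 0.031 with an estimated correlation. MHC class II genes, which present antigen, had a median of 0.75 with 6 higher when adjusted over the list alone (camera adjusted p = 9e-10, and adjusted p = 0.22 with an estimated correlation), and 35 of 36 interferon-induced genes had positive differences (median 0.47; camera adjusted p = 9e-10). It gave adjusted p = 0.45 with an estimated correlation. The MHC class II and interferon scores were lowest in FL1 of the EW+2'-FL group, and without the 3 libraries apart the medians were 0.57 and 0.32 and passed. The edgeR count against EW+2'-FL was 0 genes, with 2369 at an unadjusted p under 0.05, against 167 in DESeq2, 1 with voom, 14 without the 6 libraries with pancreatic transcripts and 18 without the 3 apart. With 1 library left out, edgeR called 2 genes without HMOs3, 1 without HMOs5 and 15 without FL5.

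Against EW+LNnT, 11 of 21 cholesterol synthesis genes were higher in EW+HMOs, and 18 when adjusted over the list alone (median 1.19; camera adjusted p = 2.1e-34). The value was adjusted p = 0.016 with an estimated correlation. Fdft1 averaged 39 ± 12.6 against 11.9 ± 1.73 CPM (n = 5 per group; log2 1.71 ± 0.22; edgeR adjusted p = 0.0011), and Fdps (1.45 ± 0.27) and Mvd (1.26 ± 0.21) each had an edgeR adjusted p of 0.023. Glucocorticoid-induced genes had no called member, with 7 of 10 lower when adjusted over the list alone (median -1.26; camera adjusted p = 8.8e-05, and adjusted p = 0.24 with an estimated correlation), and their median was 0.12 among libraries with Y-linked transcripts. MHC class II genes had a median of 0.73 (camera adjusted p = 5e-07, and adjusted p = 0.29 with an estimated correlation) and interferon-induced genes one of 0.41 (camera adjusted p = 4e-08, and adjusted p = 0.59 with an estimated correlation), which was -0.02 without the 6 libraries with pancreatic transcripts. Without FL1, LNnT1 and LNnT2 the medians were -0.32 for glucocorticoid-induced, 0.38 for MHC class II and -0.02 for interferon-induced genes, of which MHC class II passed. In all, edgeR called 92 genes (32 higher, 60 lower), DESeq2 566, voom 355, and a fit of the 2 groups alone 14. The fit with the Y-linked share as a covariate called 17, the fit without the 3 libraries apart 297 and the fit of libraries with Y-linked transcripts alone 0. Single libraries left out gave 2 genes without HMOs1, 2 without HMOs2, 34 without HMOs3, 3 without HMOs4, 23 without HMOs5, 2 without LNnT1, 37 without LNnT3, 237 without LNnT4 and 199 without LNnT5. Among libraries of other groups, FL1 left out gave 429 and FL2 160, and each control, Weaned2, Weaned3, Weaned4, Weaned5 or FL4 left out gave 47 to 58.

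For cholesterol synthesis the combined change differed from the sum of the 2 single changes. Whether the combination held the same dose of each oligosaccharide as the single groups was not given, so the sum is not at known matched doses. The log2 difference between the combined change and the sum of the 2 single changes was positive for Fdft1 (2.72 ± 0.31; edgeR adjusted p = 1e-04), Insig1 (2.27 ± 0.32; 0.0014) and Mvd (1.98 ± 0.30; 0.0021). In the list, 15 of 21 genes were called positive, and 19 when adjusted over the list alone (median 1.80; camera adjusted p = 3.1e-44). The list had adjusted p = 0.0038 with an estimated correlation. Mean expression of Fdft1 was 33.1 ± 4.95 CPM in EW, 39 ± 12.6 in EW+HMOs, 16.4 ± 5.07 in EW+2'-FL and 11.9 ± 1.73 in EW+LNnT. The clock genes Clock (-1.33 ± 0.31) and Cry1 (-1.36 ± 0.30) were negative, with 2 of 15 clock genes called and 4 when adjusted over the list alone (median -0.95; camera adjusted p = 0.0002). Camera gave adjusted p = 0.62 with an estimated correlation. Without FL1, LNnT1 and LNnT2 the clock median turned to 0.13. The heat-shock genes Hspa1a (-11.6 ± 2.49) and Hspa1b (-11.73 ± 2.51) were negative, with Hspa1a at 4710 CPM in LNnT3. Without that library they were -3.85 and -4.39 and did not pass.

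Across all genes, edgeR called 187 as non-additive (57 positive, 130 negative), with 3083 at an unadjusted p under 0.05, against 767 in DESeq2 and 512 with voom. It was 96 with the Y-linked share as a covariate, 765 without the 3 libraries apart and 4 among libraries with Y-linked transcripts. Leaving out 1 library gave 74 genes without Weaned2, 67 without Weaned3, 52 without Weaned4, 94 without Weaned5, 61 without HMOs1, 57 without HMOs2, 97 without HMOs3, 72 without HMOs4, 93 without HMOs5, 107 without FL1, 322 without FL2, 318 without FL5, 104 without LNnT1 and 123 without Control1. In the same contrast macrophage genes had a median of 0.91 (camera adjusted p = 2.8e-08, and adjusted p = 0.27 with an estimated correlation) and MHC class II genes one of 0.99 (camera adjusted p = 7.1e-08, and adjusted p = 0.27 with an estimated correlation). Both scores were lowest in FL1, LNnT1 and LNnT2, without which the medians were 0.51 and 0.55.

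Set against suckling controls, EW+HMOs showed the lectin and sterol changes seen in EW. Reg3g (log2 6.28 ± 0.75) and Reg3b (5.78 ± 0.68) rose, as did Sis from 2530 ± 823 to 7980 ± 807 CPM (1.66 ± 0.30; edgeR adjusted p = 0.0035), Mgam, maltase-glucoamylase (1.27 ± 0.28; 0.019), and Slc5a1 (1.07 ± 0.23; 0.014). Cholesterol synthesis had 17 of 21 genes higher, and 19 when adjusted over the list alone (median 1.30; camera adjusted p = 1.4e-36). It gave adjusted p = 0.012 with an estimated correlation. Fatty acid oxidation had 7 of 20 lower, and 12 when adjusted over the list alone (median -0.49; camera adjusted p = 4.6e-10, and adjusted p = 0.33 with an estimated correlation), with the thioesterase Acot1 (-2.80 ± 0.51) and Cyp4a10 (-3.80 ± 0.63) among them. Cldn3 fell (-0.84 ± 0.16; edgeR adjusted p = 0.0044), and Cyp1a1 (-3.81 ± 0.89, but -2.79 and not passing without Control5) and Ass1 (-2.68 ± 0.30) fell too. In edgeR the count was 410 genes (203 higher, 207 lower), with 1301 in DESeq2, 5227 with voom, 4966 in a fit of the 2 groups alone and 20 among libraries with Xist. Without 1 library the counts were 237 without Control1, 169 without Control3, 245 without Control4, 171 without Control5, 196 without HMOs1, 188 without HMOs2, 236 without HMOs3, 207 without HMOs4 and 235 without HMOs5. They rose to 641 without Weaned1, 697 without FL1 and 1141 without FL2.

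In EW+2'-FL against controls, Reg3g (6.16 ± 0.75), Reg3b (5.93 ± 0.69), Mptx2 (5.33 ± 1.2, and 4.75 to 6.17 with 1 library left out) and Cyp3a44 (4.33 ± 0.56, and 3.57 without FL1) rose. Cyp1a1 (-4.77 ± 0.93, and -3.76 without Control5), Cyp4a10 (-3.94 ± 0.63), Cyp2c29 (-3.11 ± 0.54) and the cornified-envelope gene Sprr2a1 (-2.73 ± 0.56) fell. Fatty acid oxidation genes had 8 of 20 lower, and 13 when adjusted over the list alone (median -0.67; camera adjusted p = 9.4e-15, and adjusted p = 0.045 with an estimated correlation). Detoxification genes had 5 of 16 lower, and 8 when adjusted over the list alone (median -0.60; camera adjusted p = 6.8e-10). The value was adjusted p = 0.040 with an estimated correlation. Suckling-type enterocyte genes were lower as a list, with 2 of 9 called (median -0.68; camera adjusted p = 1.4e-05). This became adjusted p = 0.018 with an estimated correlation. Of 10 MHC class II genes 3 fell, among them H2-Ab1 (-0.98 ± 0.24), and 5 when adjusted over the list alone (median -0.79; camera adjusted p = 1.6e-05). The list had adjusted p = 0.30 with an estimated correlation, and its score was lowest in FL1 of the group (2.71). Macrophage genes had 4 of 14 lower, with a median of -0.56 (camera adjusted p = 2.1e-05, and adjusted p = 0.32 with an estimated correlation). Cholesterol synthesis had 3 genes higher, and 8 when adjusted over the list alone (median 0.37; camera adjusted p = 0.00015). Camera gave adjusted p = 0.44 with an estimated correlation. By edgeR the count was 563 genes (236 higher, 327 lower), with 1389 in DESeq2, 2933 with voom and 123 in a fit of the 2 groups alone. With 1 library left out, edgeR called 348 without Control1, 191 without Control3, 271 without Control4, 221 without Control5, 307 without FL1 and 1452 without FL2.

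With all libraries in edgeR, EW+LNnT differed from controls in the largest number of genes, but the order of the groups depended on the fit. Reg3b (4.35 ± 0.64) and Reg3g (4.34 ± 0.69) rose, as did the glucocorticoid-induced Fkbp5 (2.01 ± 0.40) and Klf9 (1.85 ± 0.37), the clock genes Per2 (1.25 ± 0.19), Cry1 (1.40 ± 0.22) and Hlf (1.42 ± 0.21), the junction scaffold Tjp1 (0.71 ± 0.20; edgeR adjusted p = 0.029) and Sis (1.18 ± 0.30; 0.016). Cyp1a1 (-6.03 ± 0.99, and -5.02 without Control5), Sprr2a1 (-3.42 ± 0.57, from 1480 ± 676 to 138 ± 104 CPM) and Ass1 (-2.17 ± 0.29) fell. Clock genes had 8 of 15 higher, and 12 when adjusted over the list alone (median 1.18; camera adjusted p = 6.2e-09, and adjusted p = 0.20 with an estimated correlation). Glucocorticoid-induced genes had 7 of 10 higher on either count (median 1.93; camera adjusted p = 5.4e-05, and adjusted p = 0.20 with an estimated correlation), both highest in LNnT1 and LNnT2. Cholesterol synthesis did not pass as a list (median 0.24, with 2 genes higher). The edgeR count was 2348 genes (1478 higher, 870 lower), against 3617 in DESeq2, 300 without the 6 libraries with pancreatic transcripts and 1474 without the 3 libraries apart. EW+HMOs had more called genes in these last fits (345 and 1772), with voom (5227 against 3317) and with the 2 groups alone (4966 against 1626), and EW+2'-FL had 317 without the 6 libraries. With limma on FPKM the lower genes outnumbered the higher ones (909 higher and 1465 lower). Single libraries left out gave 1283 without Control1, 700 without Control3, 767 without Control5, 1115 without LNnT1 and 1016 without LNnT2.

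Taken over all 211, the early-weaning genes moved back towards controls in no oligosaccharide group beyond the level of a simulated unchanged group. Of the 211 genes called between EW and control, 56.4% moved the opposite way in EW+HMOs, 64.9% in EW+2'-FL and 68.2% in EW+LNnT against EW, where simulated unchanged groups gave 73.3%, 73.3% and 73.2% because the EW libraries are shared. Each share lay below the range of its 40 simulations (68.5% to 77.7%, 71% to 75.9% and 69.7% to 75.7%). Whether the genes moved further from controls or the simulation was unlike these libraries was not tested. Over the 107 genes also changed at least 2-fold the shares were 54.2%, 65.4% and 74.8%, with no simulation of their own. With genes chosen on one part of the EW and control libraries and measured against the other part, the shares were 39.9% (17.1 to 64 over 40 splits), 44% (27 to 65.9) and 48.4% (21.8 to 65.4), against 49.7%, 49.9% and 50.2% for simulated unchanged groups. The simulated ranges were 41.2% to 57.3%, 42.7% to 61.1% and 45% to 57.8%, and only the EW+HMOs share lay below its range. Too few genes passed in a split (a median of 16), so the 211 with the smallest p were taken instead, a change made after the counts were seen. Over the genes that did pass, in the 36 splits with 5 or more of them, the shares were 39.5% (11.1 to 80), 45% (22.2 to 77.8) and 58.2% (26.5 to 83.3), again without a simulation. For cholesterol synthesis alone, the mean list score was 4.57 in controls, 5.65 in EW, 5.85 in EW+HMOs, 4.95 in EW+2'-FL and 4.75 in EW+LNnT.

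No gene was called against EW in EW+HMOs or in EW+2'-FL, so the 3 supplement groups could share no called gene. Across 22131 genes the log2 changes correlated with r = 0.34 for EW+HMOs and EW+2'-FL, 0.35 for EW+HMOs and EW+LNnT and 0.47 for EW+2'-FL and EW+LNnT, where simulated unchanged groups set against the same EW libraries gave 0.5. With separate EW libraries for each side r was -0.06, 0 and 0.07. The covariances were 0.085, 0.107 and 0.137, against 0.119 in the simulation.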

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

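Of the tests in this part, the sex test and the splits for EW+HMOs against EW+2'-FL and EW+LNnT, for the 3 supplement groups against control and for non-additivity were fixed before their results were seen, and all others were chosen after.

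Of 270 groups of 5 values checked for a library far from the other 4, 16 passed the limit of 0.71, where chance alone would give about 1 in 20, or 14. Each value is the gap to the nearest library as a share of the group's range. Weaned1 lay apart in its group for pancreatic genes (0.955, high), Tjp1 (0.804, low), interferon-induced genes (0.767, low), glycosylation genes (0.753) and MHC class II genes (0.732, low). LNnT3 lay apart for immediate early and heat-shock genes (0.87, high) and ileal segment genes (0.737), and LNnT1 for cholesterol synthesis genes (0.758, low) and Ocln (0.747). FL1 lay apart for glucocorticoid-induced genes (0.808, high), FL2 for smooth muscle genes (0.73, high), FL3 for Reg3g (0.827) and endothelial genes (0.821), and FL5 for pancreatic genes (0.969, high). HMOs3 had a total count apart from its group (0.727, high), and HMOs4 fibroblast genes (0.744). The non-additivity contrast differed between groups by a test of the difference itself, with 187 genes.

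The first pattern weighed was the 211 genes called between EW and control. EW libraries mostly carry Y-linked transcripts and control libraries Xist, so sex could have driven the calls, but within the early-weaned groups the sex difference of these genes was 2.09% of their EW change (-5.11% to 3.87% with 1 library left out). Pancreatic RNA in Control2, Control3 and Weaned1 might have added to them, yet without the libraries holding it the median change was 106% of that in all libraries. Against a swap of Weaned1 and Control2, both (2 of 2) had a detoxification score nearer their own group, though that list was chosen after the data were seen. Weaned1 was also unlike controls for Reg3b (2330 CPM, controls 38.3 to 163) and Ass1 (2.98, controls 10.3 to 18.2). For fatty acid oxidation it lay among controls in Acot1 (38.5 CPM, controls 29.6 to 41.1, other EW libraries 4.91 to 8.32). The same held for Acadvl (318, controls 289 to 344, other EW libraries 187 to 220). With the real grouping counted, 2 of 100 splits called as many genes, and the highest other split called 464 with Control2 exchanged for Weaned1, so these 2 libraries may carry a structure of the samples that the labels do not give. Early weaning is an explanation that these tests did not contradict. Feeding state, time of collection, litter and RNA quality were not tested for this pattern. The sex test is a median over the genes and does not clear each of them. Moreover, 4 of the 5 controls were female by transcript, and age at collection may also differ.

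The second pattern was the lower cholesterol synthesis expression in EW+LNnT than in EW. The 2 LNnT libraries apart on the first component could have carried it, but without them and FL1 the median log2 difference was -0.98, near the -1 of all libraries. Among libraries with Y-linked transcripts, 2 in EW+LNnT and 4 in EW, it was -0.83. An imbalance of sex is thus a less likely source, but so few libraries cannot exclude it. A different clock phase at collection might lower these genes. With the clock score as a covariate 88.4% of the difference in list score remained (-0.80 against -0.90). LNnT3, LNnT4 and LNnT5, with clock scores like those of EW, differed by -0.74 (exact permutation p = 0.018, the smallest that so few libraries can give). Every EW+LNnT list score lay below every EW score, so any such choice of libraries gives that p, and it adds no evidence on clock phase. In LNnT3, LNnT4 and LNnT5, however, Per2 (99.4 to 158 CPM) and Cry1 (34.8 to 42) lay above every EW library (48.6 to 80.1 and 21 to 25). Hlf did not (36.8 to 40.8 against 28.9 to 49.8). A like mean score therefore does not show a like phase, and clock phase stays open. An effect of LNnT was thus not told apart from clock phase, and feeding state at collection was not tested and could act on the same genes.

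The third pattern was the distance of FL1, LNnT1 and LNnT2 from the other libraries. Pancreatic RNA could set them apart, but only 2 of the 3 held it above the libraries free of it. Lower depth might do the same, yet 1 of the 3 had a total above those of 8 other libraries, a bound that was chosen after the result was seen. A smaller share of immune cells alone may lower the T cell and MHC class II genes, but the lowest clock score of the 3 lay 0.9 above the highest of the other libraries. Without the 3 libraries 299 genes were called between EW+LNnT and EW instead of 38, so they could hide differences between groups. They come from 2 groups and had the highest mitochondrial shares (8.98% to 9.57%), so the quality of the RNA stays open, and beyond the share of immune cells no biological explanation was tested.

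Splits of the libraries into mock groups gave the following for the other contrasts. For EW+LNnT against EW, 2 of 100 splits called as many as the real 38, and the highest other split called 965, with Weaned1, Weaned2, Weaned4, LNnT1 and LNnT2 on one side, which points to a structure of the samples. For EW+2'-FL against EW+LNnT the real count was 0, so all 100 splits reached it, and the highest other split called 4252 with FL4, FL5, LNnT3, LNnT4 and LNnT5 on one side, a structure that the 3 libraries apart may account for, given their clock gap of 0.9. For EW+HMOs against EW (real 0) all 100 splits reached the count and the highest other split called 0, for EW+2'-FL against EW (real 0) the values were 100 and 31, and for EW+HMOs against EW+2'-FL (real 0) 100 and 2. For EW+HMOs against EW+LNnT 1 of 100 splits, the real grouping, reached 92 and the highest other split called 42. Against control, 1 of 100 splits reached 410 for EW+HMOs (highest other split 1), 4 reached 563 for EW+2'-FL (highest other split 1249, with FL2 exchanged for Control2, which points to a structure of the samples) and 1 reached 2348 for EW+LNnT (highest other split 3). For non-additivity 2 of 100 splits reached 187, and the highest other split called 598, again a structure of the samples.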

How the results depend on the processing

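The Y-linked covariate, the fits of libraries with Y-linked transcripts or Xist alone, and the fits without the 6 libraries with pancreatic transcripts or the 3 libraries apart were chosen after seeing the data, and all other settings before. No named gene that was called took the opposite sign under any setting, but in EW+LNnT against control the change of Hspa1a was 0 without LNnT3 and that of Retnlb 0 without LNnT2: over settings other than leaving out 1 library of the compared groups 2877 values stayed past the threshold and 754 fell short of it, and with 1 library left out 1684 and 596. Values of called gene lists kept their direction and passed 850 times, kept it without passing 422 times and changed sign 39 times, with 1607, 164 and 9 when 1 library was left out. For lists a change of sign was one of the median or of the camera direction, and values of 0 below are rounded. Cholesterol synthesis genes kept their direction in every contrast in which the list was called. Counts of calls moved most, and RLE and upper-quartile factors moved none of them by more than 1.5 times. Counts of 13592 genes were too low to test, and in simulated data 61.2% of 2-fold changes were found. The 2-fold and 0.01 limits take a part of the same calls, a fit of 2 groups or of fewer libraries has its own estimate of the spread, and for every other change below the cause was not tested. The replicate numbers gave no clear pairing of the libraries: 3 of 25 libraries correlated best with their own number in another group, where chance gives 5, and the mean correlation at the same number was 0.04 (-0.27 to 0.50), with the highest means of 2 groups, 0.16, for EW and EW+LNnT and for EW+2'-FL and EW+LNnT.

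With a 2-fold limit added, genes called were 107 for EW against control, 20 for EW+LNnT against EW, 41 for EW+HMOs against EW+LNnT, 201 for EW+HMOs against control, 279 for EW+2'-FL against control and 878 for EW+LNnT against control. At an adjusted p under 0.01, genes called were 48 for EW against control, 4 for EW+LNnT against EW, 2 for EW+HMOs against EW+LNnT, 124 for EW+HMOs against control, 135 for EW+2'-FL against control, 408 for EW+LNnT against control and 28 for non-additivity. With DESeq2, genes called were 658 for EW against control, 55 for EW+HMOs against EW, 48 for EW+2'-FL against EW, 409 for EW+LNnT against EW, 86 for EW+2'-FL against EW+LNnT, 167 for EW+HMOs against EW+2'-FL, 566 for EW+HMOs against EW+LNnT, 1301 for EW+HMOs against control, 1389 for EW+2'-FL against control, 3617 for EW+LNnT against control and 767 for non-additivity. With voom and quality weights, genes called were 4775 for EW against control, 161 for EW+HMOs against EW, 10 for EW+2'-FL against EW, 156 for EW+LNnT against EW, 1 for EW+HMOs against EW+2'-FL, 355 for EW+HMOs against EW+LNnT, 5227 for EW+HMOs against control, 2933 for EW+2'-FL against control and 512 for non-additivity. With no count filter, genes called were 130 for EW against control, 15 for EW+LNnT against EW, 35 for EW+HMOs against EW+LNnT, 1508 for EW+LNnT against control and 84 for non-additivity. With the 2 groups alone, genes called were 1638 for EW against control, 1 for EW+LNnT against EW, 14 for EW+HMOs against EW+LNnT, 4966 for EW+HMOs against control and 123 for EW+2'-FL against control. With the Y-linked share as a covariate, genes called were 55 for EW against control, 6 for EW+LNnT against EW, 17 for EW+HMOs against EW+LNnT, 171 for EW+HMOs against control, 240 for EW+2'-FL against control and 96 for non-additivity. Without the 3 libraries apart, genes called were 1135 for EW against control, 2 for EW+2'-FL against EW, 299 for EW+LNnT against EW, 18 for EW+HMOs against EW+2'-FL, 297 for EW+HMOs against EW+LNnT, 1772 for EW+HMOs against control, 1474 for EW+LNnT against control and 765 for non-additivity. With limma on FPKM and a pseudocount of 1, genes called were 1 for EW+2'-FL against EW, 19 for EW+LNnT against EW and 627 for EW+HMOs against control. With a pseudocount of 0.1 on FPKM, genes called were 1 for EW+2'-FL against EW and 18 for EW+LNnT against EW. With unfiltered FPKM, genes called were 1 for EW+2'-FL against EW, 16 for EW+LNnT against EW, 55 for EW+HMOs against EW+LNnT and 100 for non-additivity. With the stricter filter, genes called were 70 for EW+LNnT against EW, 153 for EW+HMOs against EW+LNnT and 294 for non-additivity. With the replicate number as a block, genes called were 20 for EW+LNnT against EW and 57 for EW+HMOs against EW+LNnT. Without the 6 libraries with pancreatic transcripts, genes called were 3 for EW+LNnT against EW, 14 for EW+HMOs against EW+2'-FL, 50 for EW+HMOs against EW+LNnT, 317 for EW+2'-FL against control and 300 for EW+LNnT against control. Among libraries with Y-linked transcripts, genes called were 0 for EW+LNnT against EW, 0 for EW+HMOs against EW+LNnT and 4 for non-additivity. Among libraries with Xist, genes called were 58 for EW+HMOs against EW+LNnT, 20 for EW+HMOs against control and 3813 for EW+LNnT against control. With 1 library of the compared groups left out in turn, genes called ranged from 58 to 530 for EW against control, 0 to 1 for EW+HMOs against EW, 0 to 2 for EW+2'-FL against EW, 5 to 161 for EW+LNnT against EW, 0 to 4 for EW+2'-FL against EW+LNnT, 0 to 15 for EW+HMOs against EW+2'-FL, 2 to 237 for EW+HMOs against EW+LNnT, 169 to 369 for EW+HMOs against control, 191 to 1452 for EW+2'-FL against control, 700 to 2813 for EW+LNnT against control and 52 to 322 for non-additivity. Libraries of other groups act through the shared fit. Without FL1 genes called were 360 for EW against control, 219 for EW+LNnT against EW, 429 for EW+HMOs against EW+LNnT, 697 for EW+HMOs against control and 3310 for EW+LNnT against control. Without FL2 they were 404, 120, 160, 1141 and 3271 for the same contrasts, and for EW+HMOs against control 641 without Weaned1. Non-additivity had 123 without Control1.

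Of 44 lists, the preset correlation called 12 for EW against control. Against EW it called 22 for EW+HMOs, 13 for EW+2'-FL and 18 for EW+LNnT, and against control 12, 16 and 10. It called 13 for EW+2'-FL against EW+LNnT, 17 for EW+HMOs against EW+2'-FL, 19 for EW+HMOs against EW+LNnT and 13 for non-additivity. With an estimated correlation, gene lists called were 2 for EW against control, 1 for EW+HMOs against EW, 2 for EW+2'-FL against EW, 0 for EW+LNnT against EW, 0 for EW+2'-FL against EW+LNnT, 1 for EW+HMOs against EW+2'-FL, 1 for EW+HMOs against EW+LNnT, 1 for EW+HMOs against control, 4 for EW+2'-FL against control, 0 for EW+LNnT against control and 1 for non-additivity. With fry, gene lists called were 5 for EW against control, 1 for EW+HMOs against EW, 2 for EW+2'-FL against EW, 1 for EW+LNnT against EW, 0 for EW+2'-FL against EW+LNnT, 1 for EW+HMOs against EW+2'-FL, 2 for EW+HMOs against EW+LNnT, 6 for EW+HMOs against control, 8 for EW+2'-FL against control, 5 for EW+LNnT against control and 4 for non-additivity. Among libraries with Y-linked transcripts, gene lists called were 20 for EW+2'-FL against EW, 10 for EW+LNnT against EW, 6 for EW+HMOs against EW+LNnT and 6 for non-additivity. Without the 6 libraries with pancreatic transcripts, gene lists called were 11 for EW+HMOs against EW+LNnT. Without the 3 libraries apart, gene lists called were 10 for EW+HMOs against EW+LNnT. The share of early-weaning genes moved back fell to 39.9%, 44% and 48.4% with split libraries for EW+HMOs, EW+2'-FL and EW+LNnT, where the shared EW libraries no longer add to it. Correlations between supplement groups were 0.44 (EW+HMOs and EW+2'-FL), 0.39 (EW+HMOs and EW+LNnT) and 0.52 (EW+2'-FL and EW+LNnT) over genes changed at least 2-fold. Simulated unchanged groups gave 0.58 for each pair there. Over genes with at least 5 CPM the correlations were 0.13, 0.02 and 0.44, against 0.5, 0.5 and 0.51 in the simulation. With split EW libraries they were -0.06, 0 and 0.07.

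Without the 6 libraries with pancreatic transcripts, the sign changed to fatty acid oxidation (0.03), interferon (-0.02) and pancreas (0.06) for EW+HMOs against EW, clock (-0.26) for EW+LNnT against EW, clock (0.73) and pancreas (0.09) for EW+2'-FL against EW+LNnT and interferon (-0.02), clock (0.45) and T cells (-0.10) for EW+HMOs against EW+LNnT. Without the 3 libraries apart, the sign changed to MHC class II (0.03), interferon (0.15), clock (-0.20) and pancreas (-8.68) for EW+LNnT against EW, clock (0.34) and pancreas (9.35) for EW+2'-FL against EW+LNnT, proliferation (0) for EW+HMOs against EW+2'-FL, interferon (-0.02), clock (0.45) and T cells (-0.10) for EW+HMOs against EW+LNnT and clock (0.13) and T cells (-0.40) for non-additivity. Among libraries with Y-linked transcripts, the sign changed to MHC class II (0), interferon (0.01), crypt stem cells (0.05), glucocorticoid (-0.25), clock (-0.23) and pancreas (-8.48) for EW+LNnT against EW, Paneth cells (-0.09), crypt stem cells (0.01), clock (0.79), immediate early (0.33), smooth muscle (-0.11) and pancreas (8.84) for EW+2'-FL against EW+LNnT, smooth muscle (0.07) for EW+HMOs against EW+2'-FL, crypt stem cells (-0.11), glucocorticoid (0.12), clock (0.46) and T cells (-0.12) for EW+HMOs against EW+LNnT and T cells (-0.56) for non-additivity. With 1 library of the compared groups left out, values on both sides of 0 came from fatty acid oxidation (-0.19 to 0.03), interferon (-0.02 to 0.27), pancreas (-10.9 to 0) and ileal segment (-0.02 to 0.38) for EW+HMOs against EW, immediate early (-2.42 to 0.01) and smooth muscle (-0.05 to 0.90) for EW+2'-FL against EW+LNnT, proliferation (-0.01 to 0.27) and smooth muscle (-0.91 to 0.10) for EW+HMOs against EW+2'-FL and antimicrobial (-0.01 to 0.64) for EW+HMOs against EW+LNnT.

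Among libraries with Y-linked transcripts, the sign changed to Tnf (-0.01) and Il1b (-0.05) for EW+HMOs against EW. With voom and quality weights, the sign changed to Tjp1 (-0.09) for EW+HMOs against EW, Tjp1 (-0.02) for EW+2'-FL against EW, Ocln (-0.18) for EW+2'-FL against control and Tnf (-0.26) and Lct (0.03) for EW+LNnT against control. With limma on FPKM and a pseudocount of 1, the sign changed to Tjp1 (-0.04) for EW+HMOs against EW, Tjp1 (-0.01) for EW+2'-FL against EW, Muc2 (-0.14) and Lct (-0.09) for EW+LNnT against EW and Ocln (-0.07) for EW+2'-FL against control. With a pseudocount of 0.1 on FPKM, the sign changed to Tjp1 (-0.04) for EW+HMOs against EW, Sis (-0.01) and Tjp1 (-0.01) for EW+2'-FL against EW, Il1b (-0.18), Muc2 (-0.16) and Lct (-0.09) for EW+LNnT against EW and Ocln (-0.07) for EW+2'-FL against control. With unfiltered FPKM, the sign changed to Tjp1 (-0.04) for EW+HMOs against EW, Tjp1 (-0.01) for EW+2'-FL against EW, Muc2 (-0.14) and Lct (-0.09) for EW+LNnT against EW, Ocln (-0.07) for EW+2'-FL against control and Tnf (-0.03) for EW+LNnT against control. Without the 6 libraries with pancreatic transcripts, the sign changed to Tjp1 (-0.12) and Cldn3 (0.01) for EW+HMOs against EW, Sis (-0.16) and Tjp1 (-0.11) for EW+2'-FL against EW, Sis (-0.11) for EW+LNnT against EW and Lct (0.10), Il1b (0.58) and Muc2 (0.20) for EW+LNnT against control. Without the 3 libraries apart, the sign changed to Ocln (-0.08) and Tjp1 (-0.12) for EW+2'-FL against EW, Sis (-0.04) for EW+LNnT against EW, Ocln (-0.31) for EW+2'-FL against control and Lct (0.02), Il1b (0.37) and Muc2 (0.09) for EW+LNnT against control. With the Y-linked share as a covariate, the sign changed to Lct (-0.05) for EW+HMOs against control. Among libraries with Xist, the sign changed to Muc2 (0.20), Il1b (0.18) and Tnf (0.02) for EW+HMOs against control. With no count filter, the sign changed to Ocln (-0.01) for EW+2'-FL against control. With the replicate number as a block, the sign changed to Ocln (-0.05) for EW+2'-FL against control and Tnf (-0.99) for EW+LNnT against control. With 1 library of these groups left out, both signs appeared for Tjp1 (-0.12 to 0.06) and Cldn3 (-0.17 to 0.01) for EW+HMOs against EW, Tnf (-0.22 to 1.03), Ocln (-0.07 to 0.33), Sis (-0.07 to 0.31) and Tjp1 (-0.12 to 0.18) for EW+2'-FL against EW, Il1b (-0.23 to 0.90), Sis (-0.05 to 0.27), Muc2 (-0.17 to 0.42), Lct (-0.12 to 0.25) and Reg3g (-0.74 to 0.10) for EW+LNnT against EW and Lct (-0.05 to 0.23) and Muc2 (-0.45 to 0.01) for EW+HMOs against control. Again with 1 library of these groups left out, both signs appeared for Ocln (-0.30 to 0.10) for EW+2'-FL against control and Tnf (-0.96 to 0.44) for EW+LNnT against control.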

Other observations

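All values in this part were chosen after the results were seen.

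Cyp1a1 and Cyp1a2, which are under the aryl hydrocarbon receptor, had lower means in every early-weaned group than in controls. Cyp1a1 averaged 68.4 ± 79.7 CPM in controls (206 CPM in Control5 and at most 59.5 CPM in the others) and 2.61, 4.88, 2.49 and 1.03 CPM in EW, EW+HMOs, EW+2'-FL and EW+LNnT, and Cyp1a2 1.13 CPM in controls and at most 0.0189 CPM in the means of the other groups (n = 5 per group). The list of 6 receptor targets scored 3.06 ± 0.34 in controls and 1.57 ± 0.42 in EW (exact permutation p = 0.0079, adjusted p = 0.07 over the lists), and its camera adjusted p was 0.11. Other members did not follow, with Tiparp at 38 CPM in controls and 37.9 in EW and Nqo1 at 30.6 and 36.1. Tiparp was higher in EW+LNnT than in controls (68.4 CPM, edgeR adjusted p = 0.0099). Cyp1b1 was higher in EW+2'-FL than in controls (6.74 against 3.08 CPM, edgeR adjusted p = 0.023). The cornified-envelope genes Sprr2a1 and Sprr2a2 averaged 1480 and 1420 CPM in controls and 375 and 370 CPM in EW (edgeR adjusted p = 0.083 and 0.086).

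Transcripts of cells around the epithelium varied between libraries and between groups, with smooth muscle medians of -0.47 for EW+HMOs and -0.54 for EW+LNnT against EW. The adipocyte gene Adipoq averaged 0.512 CPM in controls, 2.15 in EW, 0.514 in EW+HMOs, 3.58 in EW+2'-FL and 0.075 in EW+LNnT, and the adipocyte score ranged from -2.07 to 4.42 over the 25 libraries. Smooth muscle scores ranged from 5.28 to 7.86, with the highest in FL2. Bco1, which cleaves beta-carotene, averaged 7.22 CPM in controls, 20.3 in EW, 149 in EW+HMOs, 33.9 in EW+2'-FL and 72.8 in EW+LNnT without passing against EW. Hspa1a averaged 946 ± 2100 CPM in EW+LNnT, with 4710 CPM in LNnT3. Control2 had Y-linked transcripts at 43.5% of the median of libraries without Xist and Xist at 61.8% of the median of libraries without Y-linked transcripts.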
